A study of Mus musculus with 2 samples.

How the data were processed

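MicroRNA sequencing libraries were made from the hippocampus of 14-day-old female B6CASTF1/J mice, in 2 biological replicates with 1 technical replicate each. Each replicate is labelled with 3 females, and the labels limit the RNA to sizes under 30. The tissue label reads as a layer of hippocampus, without saying which layer. Per the labels, the total RNA was prepared with a multiplexed microRNA library protocol, and both libraries belong to the same group.

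The deposited tables hold raw counts of reads per microRNA gene, 1 table per library, made on assembly mm10 (GRCm38) with GENCODE annotation release M21 per the text that accompanies the deposited counts. The aligner and the counting program are not given in the sources used here. Each table has 3 count columns without a header, read as unstranded counts and counts on each strand. The strand column with the larger total was taken as sense and used throughout. The tables also hold lines for unmapped, multi-mapping, unassigned and ambiguous reads, which stayed out of library sizes and tests. Within a column these lines and the genes sum to the same total, so a multi-mapping read is not also counted in a gene.

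Replicate 1 had 13195465 reads, of which 36.1% were assigned to microRNA genes, 40.8% were multi-mapping, 17.1% were unmapped and 5.98% matched no annotated microRNA gene on the sense strand. Replicate 2 had 7838361 reads, with 36.4% assigned, 37.1% multi-mapping, 20.6% unmapped and 5.82% matching no such gene. The mean assigned share was 36.2% ± 0.198 (SD, n = 2). Sense counts summed to 4764797 and 2852269, and opposite-strand counts came to 6.26% and 6.36% of these. A count is for a precursor gene, and the products of its 2 arms are not separated. All 2202 gene identifiers matched the M21 annotation, which gave symbols, coordinates and host genes.

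Levels are CPM, computed here from the deposited counts and the total assigned to microRNA genes, with mean and SD over the 2 libraries. A gene was called detected at 10 counts in both libraries. Log2 ratios of replicate 2 to replicate 1 used library sizes scaled by TMM in edgeR 4.0.16 under R 4.3.3, for 450 genes with a summed count of at least 20. Each gene was tested with a two-sided exact binomial test against the share expected from the scaled sizes, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation is edgeR's common dispersion of a model with an intercept only, with an interval from 100 bootstrap draws over genes. Exact Clopper-Pearson intervals at 95% were used for shares and ratios, and the correlation interval rests on 1000 bootstrap draws. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression, each member drawn from its 40 nearest genes, and this percentile describes these libraries and is not a p-value. Members were drawn singly, so random lists do not keep neighbouring genes together. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

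Genes sharing a run of at least 20 bases with a microRNA gene elsewhere, 1089 of 2202, were treated as uncertain. The genes named were fixed by rule before the data were examined: the 20 with the highest mean level, the 4 most abundant detected members of each of 16 lists, and the 5 with the largest ratio in each direction among genes with a mean count of at least 100 that passed the test. This rule took 70 genes. Other genes named in the text, Mir203, Mir200a, Mir182, Mir141, Mir544, Mir379, Mir539, Mir211, Mir1912, Mir764, Gm22650, Gm24627, Mir26b, the genes with opposite-strand counts and copies of several families, were chosen after their values were seen.

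The binomial step was tested on simulated data for 450 genes with counting noise only. It called 0.8% of 250 genes with no change, 81% of 100 genes with a 2-fold change and 92% of 100 genes with a 4-fold change. The dispersion step returned 0.207 for a simulated coefficient of variation of 0.2 over 438 genes and 0.497 for 0.5 over 427 genes. All simulated genes had the same coefficient of variation, so genes of unequal spread were not tested. The simulated binomial step used the known library sizes, so it did not test the scaling.

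Alternatives fixed beforehand were the unstranded column, DESeq2 1.42.0 size factors, total counts as library sizes, no filter or a summed count of at least 200, other detection minimums, thinning of the deeper library, leaving out the most abundant gene, leaving out each replicate, pseudocounts of 0.1 and 10, the median gene-wise dispersion of DESeq2 and an adjusted p under 0.01. A removed GC trend and the exclusion of genes with shared bases were added after seeing the data. The opposite-strand counts of 1 further gene are not reported here. Per-base signal tracks and alignments are not analysed here.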

Results

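Small RNA from the hippocampus of 14-day-old female mice was sequenced to measure microRNAs, the short RNAs that bind messenger RNAs and lower their translation or stability. The mice were B6CASTF1/J, the first-generation cross of the C57BL/6J and CAST/EiJ strains. The labels give 1 group with 2 biological replicates, and each replicate is labelled with 3 females, so a library stood for a pool and not for a single animal. With 1 group there was no contrast between conditions. Each pool had 1 library, so a difference between the pools cannot be told apart from a difference in library preparation. The comparisons that follow describe the microRNA profile, the levels of gene groups fixed before the data were examined, and the difference between the 2 pools. Counts per microRNA gene summed to 4764797 in replicate 1 and 2852269 in replicate 2. A count of 0 allowed a level of up to 0.630 CPM (counts scaled to the library's assigned total) in replicate 1 and 1.05 in replicate 2. Intervals, floors and per-gene tests on these reads cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

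Among reads assigned to genes, which leave out the multi-mapping 39.0% of all reads, the 10 leading genes were let-7 members, microRNAs of the imprinted Dlk1-Dio3 region, Mir99a, Mir139 and Mir744. Mirlet7b, a member of the let-7 family that accumulates as neural tissue matures, was the most abundant gene at 103560 ± 21543 CPM (SD, n = 2). Mir127, a microRNA made from the maternal copy of the Dlk1-Dio3 region opposite Rtl1, followed at 66820 ± 20215 CPM. Mirlet7i stood at 64936 ± 4506, Mir99a at 63918 ± 19026, Mir139 at 61110 ± 7525 and Mirlet7g at 57974 ± 770.2 CPM. Mir127 and Mir99a lay below Mirlet7i, Mir139 and Mirlet7g in replicate 1 and above them in replicate 2. Mir770, Mirlet7d, Mir744 and Mir433 completed the 10 leading genes at 31681 ± 2628, 25553 ± 3178, 23986 ± 16204 and 22194 ± 593 CPM. The place of Mir744 rested on replicate 1, at 35445 CPM. In replicate 2 it stood at 12528 CPM, below Mir99b at 25109.

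These 10 genes held 52.2% ± 0.0713 (SD, n = 2) of the counts, and 74 genes held 90%. In all, 409 of 2202 annotated microRNA genes (18.6%) had at least 10 counts in both libraries, and 1414 had none in either. In the mouse genome build GRCm38, Mirlet7b (ENSMUSG00000065564.1) lies at chromosome 15, 85707319 to 85707403, in an exon of Lncppara. Mir127 (ENSMUSG00000070076.2) lies at chromosome 12, 109592846 to 109592915. Mir139 (ENSMUSG00000065446.1) lies at chromosome 7, 101475376 to 101475443, within an intron of Pde2a. The genes at ranks 11 to 20 were Mir99b, Mirlet7e, Mir23b, Mir382, Mir652, Mir126a, Mir149, Mir487b, Mir100 and Mir191, from 19593 ± 7801 down to 9867 ± 1025 CPM. Of the 20 leading genes, Mir23b and Mir487b share at least 20 bases with another microRNA gene and are uncertain. Mirlet7b, Mirlet7i and Mirlet7g share a run of 19 bases with another let-7 gene, just under this limit. Mirlet7e, Mir126a and Mir191 overlap a microRNA gene on the opposite strand, and their levels fell to at most 0.224 CPM when strand was ignored.

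The gene lists fixed before the data were examined differed widely in their share of the counts. The 12 let-7 genes, all detected, held 27.9% ± 2.5 (SD, n = 2). Of these 12, 6 share at least 20 bases with another microRNA gene and are uncertain, so this share also holds for assigned reads only. The imprinted Dlk1-Dio3 cluster, a maternally expressed array on chromosome 12, held 21.7% ± 1.76 with 49 of 52 genes detected. Microglia and other immune cells had 7 of 8 genes detected and 0.218% ± 0.0412, led by Mir150, which is abundant in lymphocytes, at 914 ± 109 CPM. Neuron-enriched microRNAs held 9.67% ± 2.12 with 18 of 21 genes detected. This list was led by Mir127, which held 6.68% ± 2.02 of the counts by itself and is also counted in the Dlk1-Dio3 cluster. By mean level it was followed by Mir132, an activity-induced microRNA, at 6070 ± 1968 CPM. Mir137 stood at 5339 ± 1678 and Mir128-1 at 4973 ± 3440 CPM. Mir132 lay below Mir137 and Mir128-1 in replicate 1 and above them in replicate 2. Of the 18 tested genes of this list 11, Mir128-1 among them, share at least 20 bases with another microRNA gene and are uncertain, and the copies of Mir124a summed to 12 and 20 counts and those of Mir9 to 511 and 234, so the share and the order hold for assigned reads only.

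**Figure D1:**
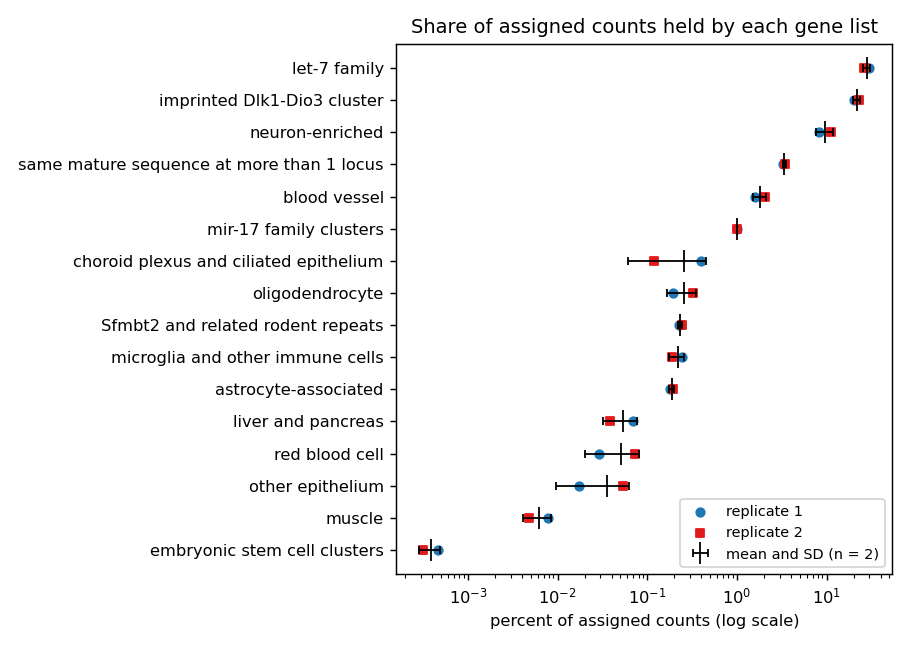
Percent of assigned counts (log axis) held by each of 16 gene lists. Circles are replicate 1, squares are replicate 2, and ticks with bars are the mean and SD (n = 2). The let-7 family at 27.9% lies at the top, and the choroid plexus and ciliated epithelium list ranges from 0.119% to 0.395%.

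Lists for vessels, other glia and blood held small shares. Blood vessel microRNAs held 1.82% ± 0.310 (SD, n = 2) with 3 of 5 genes detected, mostly from the endothelial Mir126a at 13415 ± 4878 CPM and from Mir143, which is abundant in smooth muscle, at 4517 ± 1714. The oligodendrocyte list held 0.256% ± 0.0897 with 3 of 4 genes detected, led by Mir219a-2, a microRNA of oligodendrocyte differentiation, at 1915 ± 945 CPM, which is uncertain because it shares at least 20 bases with another microRNA gene. Mir338 of the same list stood at 627 ± 52.6. The astrocyte-associated list held 0.188% ± 0.0109 with 6 of 6 genes detected, led by Mir29a at 1504 ± 13.3 CPM. Red blood cell microRNAs held 0.0507% ± 0.0306 with 3 of 5 genes detected, mostly Mir451a, which red cells carry in quantity, at 440 ± 315 CPM.

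Other tissues gave small shares. Choroid plexus and ciliated epithelium microRNAs held 0.257% ± 0.195 (SD, n = 2) with 4 of 7 genes detected. Other epithelium held 0.0358% ± 0.0262 with 8 of 10 detected, liver and pancreas 0.0543% ± 0.0225 with 3 of 6, and muscle 0.00628% ± 0.00213 with 1 of 9, Mir206 at 54.2 ± 28.1 CPM. The proliferation-linked mir-17 family clusters held 0.995% ± 0.00255 with 10 of 15 detected, led by Mir93 at 4136 ± 462 CPM. The Sfmbt2 intronic cluster and related rodent repeats held 0.234% ± 0.0123 with 8 of 81 detected, led by Mir467d at 1339 ± 254 CPM, and all 8 share at least 20 bases with another gene. None of 14 genes of the embryonic stem cell clusters was detected, and these genes summed to 22 and 9 counts. The genes with 1 mature sequence at several loci held 3.38% ± 0.116 with 43 of 60 detected. They were led by Mir128-1 at 4973 ± 3440 CPM and Mir138-1 at 4957 ± 3107 CPM. Both share at least 20 bases with another gene and are uncertain.

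Among genes with a mean count of at least 100, the largest differences between the 2 pools included microRNAs from introns of Htr2c, which encodes a serotonin receptor, and epithelial microRNAs. Mir1298 (ENSMUSG00000080331.1), within an Htr2c intron at chromosome X, 147064905 to 147065002, had 18326 counts in replicate 1 and 251 in replicate 2, a log2 ratio of replicate 2 to replicate 1 of -5.32 (95% counting interval -5.51 to -5.15). Mir1264 and Mir448, in introns of the same gene, gave -3.12 (-3.72 to -2.62) and -2.43 (-2.77 to -2.12). Mir301, within an intron of Ska2, gave -3.28 (-3.48 to -3.09), and Mir148a gave -2.45 (-2.85 to -2.10). In the other direction, Mir31 (ENSMUSG00000065408.1) at chromosome 4, 88910557 to 88910662, gave 3.37 (3.19 to 3.56) and Mir183, of a sensory and epithelial cluster, gave 3.27 (2.89 to 3.68). Mir429 of the mir-200 family gave 2.81 (2.48 to 3.16), Mir543 gave 2.71 (2.65 to 2.77) and Mir107 gave 2.32 (2.27 to 2.37). Mir107 shares at least 20 bases with another microRNA gene and is uncertain.

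**Figure D2:**
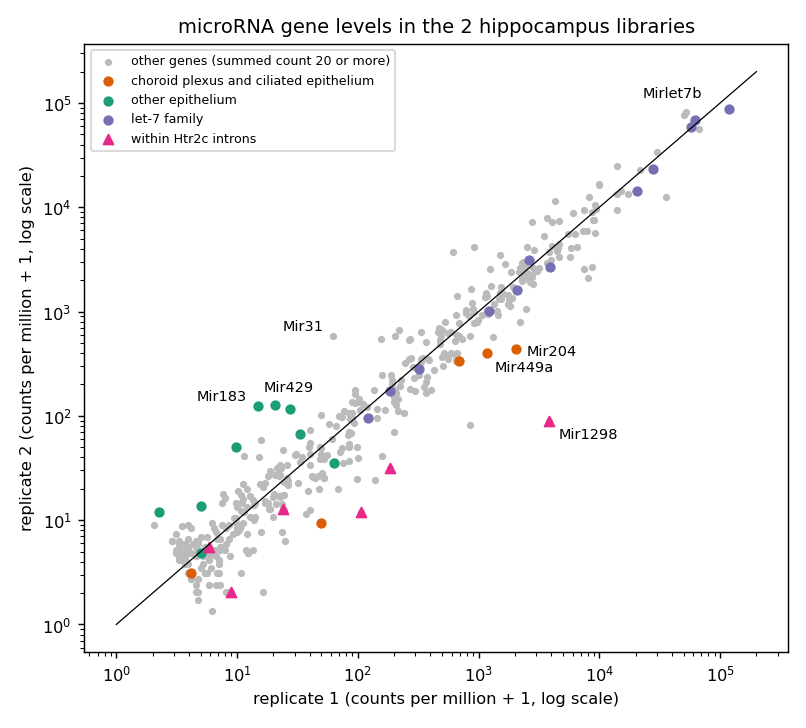
Level of each microRNA gene with a summed count of at least 20 in replicate 1 and replicate 2, in CPM plus 1 on log axes. The line marks equal levels. Mir1298 lies below the line with 18326 counts in replicate 1 and 251 in replicate 2, and most of the other epithelium genes lie above it.

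Of 450 microRNA genes with a summed count of at least 20, 145 were higher and 141 lower in replicate 2 by the exact binomial test with Benjamini-Hochberg adjustment, and 164 did not pass. This test compares these 2 libraries, not conditions. With library sizes taken as total counts in place of TMM scaling, the log2 ratios shifted by -0.12, and the split became 125 higher and 168 lower. Of the named genes that passed, Mir382 and Mir652 then changed direction. The ratio exceeded 2-fold in 96 genes, 47 higher and 49 lower in replicate 2. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.972 (bootstrap 95% interval 0.964 to 0.978) and Spearman's rho 0.962. The common biological coefficient of variation was 41.5%, or 0.415 (0.366 to 0.461), by edgeR's common dispersion and 0.209 by the median gene-wise dispersion of DESeq2. The interval resamples genes of these 2 libraries, so it does not cover the spread among other pools. With 1 library per pool, these values also include differences in library preparation. The labels name the libraries as separate biological replicates, and they were counted as 2 samples.

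Choroid plexus and ciliated epithelium microRNAs were lower in replicate 2. Of 5 tested genes 4 passed, all lower, and the list's share was 0.395% (exact 95% interval 0.390 to 0.401) in replicate 1 and 0.119% (0.115 to 0.123) in replicate 2. Mir204, abundant in choroid plexus and located in an intron of Trpm3, gave a log2 ratio of -2.08 (-2.17 to -2.0). Mir449a, a microRNA of multiciliated cells in an intron of Cdc20b, gave -1.42 (-1.52 to -1.33). Mir34c and Mir34b, also abundant in ciliated cells, gave -0.92 (-1.03 to -0.82) and -2.39 (-3.09 to -1.81). The list's median was -1.42, and 3 of 10000 random lists of the same size and mean expression were as low. Those lists drew genes singly, while Mir34c and Mir34b are neighbouring genes that may move together.

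Other epithelium microRNAs were higher in replicate 2. Of 9 tested genes 7 were higher and 1, Mir203, was lower, and the list's share was 0.0173% (0.0161 to 0.0185) in replicate 1 and 0.0543% (0.0517 to 0.0571) in replicate 2. Mir200c and Mir200b, microRNAs that maintain epithelial identity, gave log2 ratios of 2.26 (1.96 to 2.57) and 1.14 (0.83 to 1.46), beside Mir429 and Mir183 named above. The median of 2.26 was reached by 0 of 10000 random lists. Mir429, Mir200a and Mir200b are neighbouring genes, as are Mir182 and Mir183, and Mir141 and Mir200c. Random lists drew genes singly, so this result does not allow for neighbours that move together. Mir183 rested on a mean of 209 counts and Mir429 on a mean of 226.5.

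Astrocyte-associated microRNAs had a median log2 ratio of 0.66, at the 98.3 percentile of random lists, with 4 of 6 genes higher in replicate 2 and none lower. The count was 5 when adjusted over the list alone. Mir29c gave 0.77 (0.62 to 0.92), Mir29b-2 gave 1.12 (0.75 to 1.5), both uncertain because they share at least 20 bases with another gene, and Mir29a 0.14 (0.09 to 0.19). Mir193b did not pass, at 0.00 (-0.23 to 0.23). The call was lost when genes sharing at least 20 bases with another gene were left out (median 0.14, percentile 59.6) and when a summed count of at least 200 was required (0.45, 91.4). The 98.3 percentile lies close to the edge of the central 95%, and 14 lists were examined. Mir29b-2 and Mir29c are neighbouring genes, as are Mir29a and Mir29b-1. Random lists drew genes singly, so the percentile does not allow for neighbours that move together.

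The other lists lay within the central 95% of random lists, and each range given with a median is over the alternatives that gave a value. The oligodendrocyte median was 0.68 (percentile 94.96, range 0.24 to 0.67) with 2 of 3 genes higher, Mir219a-2 at 1.17 (1.12 to 1.22) among them, while Mir338 at -0.05 (-0.14 to 0.04) did not pass. For microglia and other immune cells the median was -0.29 (percentile 20.6, range -0.63 to -0.21), with 3 of 7 lower, including Mir21a at -0.71 (-0.81 to -0.61) and Mir155 at -0.63 (-0.92 to -0.35). Red blood cell genes had a median of -0.17 (percentile 39.6, range -0.29 to 0.71), and their share was higher in replicate 2 (0.0723% against 0.0290%), with Mir451a at 1.73 (1.62 to 1.84) and with Mir144 and Mir486 not past the test. Blood vessel genes had a median of -0.46 (percentile 8.74, range -0.58 to -0.42) while their share was higher in replicate 2, with Mir126a at 0.88 (0.86 to 0.90) and Mir143 at -0.67 (-0.71 to -0.64). Liver and pancreas gave -0.18 (percentile 30.2, range -0.63 to -0.12), with Mir375, abundant in pancreatic islets, at -0.83 (-0.94 to -0.73). The 2 tested muscle genes were too few for a median.

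Among the larger groups, 9 neuron-enriched genes were higher and 7 lower, with Mir132 at 0.80 (0.77 to 0.82) and Mir128-1 at -1.42 (-1.46 to -1.38). Of the let-7 genes 3 were higher and 7 lower, with a median of -0.14 (percentile 15.4, range -0.27 to 0.01). Of the Dlk1-Dio3 genes 24 were higher and 18 lower, with a median of 0.05 (percentile 72.8, range -0.08 to 0.17). The neuron-enriched median was 0.10 (percentile 66.3, range -0.09 to 0.28). The mir-17 clusters had 6 genes higher and 4 lower (median 0.24, percentile 80.4, range -0.11 to 0.25), and the Sfmbt2 repeats 2 higher and 3 lower (median -0.04, percentile 53.5, range -0.16 to 0.27). The genes with 1 mature sequence at several loci had 22 higher and 11 lower (median 0.26, percentile 96.6, range 0.08 to 0.30), or 23 higher and 11 lower when adjusted over the list alone. In every list except this one and the astrocyte-associated list, the counts were the same adjusted over the list alone.

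Within the Mir379 to Mir410 array of the Dlk1-Dio3 region, at chromosome 12, 109709060 to 109743795, members had log2 ratios from -1.21 to 2.71. Mir543 was highest at 2.71, and Mir544, with 52 and 12 counts, was lowest at -1.21 (-2.29 to -0.33). Mir382, the most abundant named member, gave 0.05 (0.03 to 0.06), and Mir379 gave -0.18 (-0.20 to -0.15). The SD of the log2 ratio over 34 tested members was 0.71, and 0.50 without these extremes. The other 416 tested genes had an SD of 0.99. They were not matched to the array on counts, so the 2 SDs do not show that the array varied less.

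**Figure D3:**
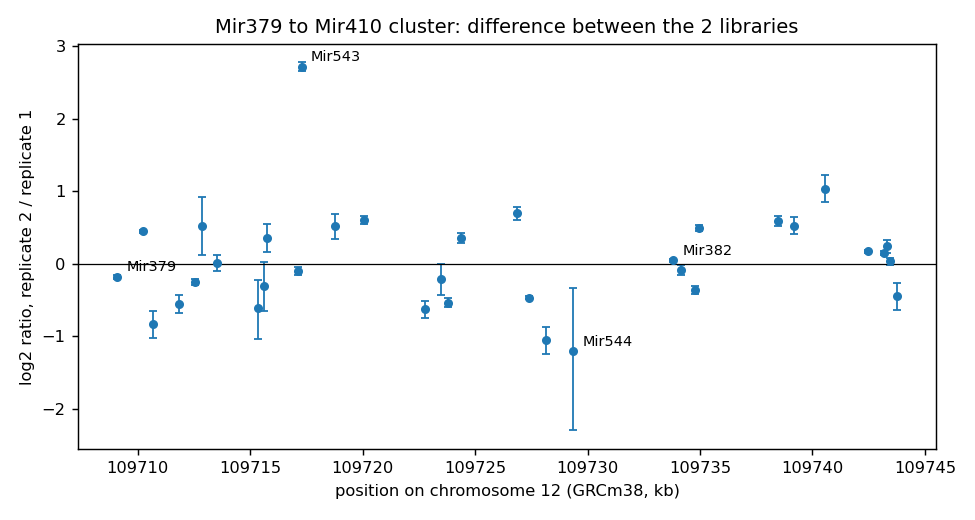
Log2 ratio of replicate 2 to replicate 1 for 34 microRNA genes of the Mir379 to Mir410 array by position on chromosome 12 (kb). Bars are 95% counting intervals. Mir543 at 2.71 stands above the rest, and Mir544 at -1.21 has a wide interval.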

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

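Of the tests in this part, those of counting error, of choroid plexus share, of a shift of the whole array and of multi-mapping reads were chosen after the results were seen, while the tests of GC content were set before their results were seen. For counting error in the choroid and Htr2c group, a looser criterion that would have excluded it for the whole group was tried after the first gave no decision, and the first was kept.

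The strand column opposite to the microRNA genes was not used in the comparisons, and 99.95% and 99.94% of its counts lay in genes that overlap another microRNA gene on the opposite strand. Outside such pairs, the 3 genes reported here had opposite-strand counts above the floor of 3 in both libraries. Mir7654, within an exon of Arglu1, had 48 opposite-strand counts (25 and 23) beside 4 and 3 sense counts. Mir5620, opposite Clcn4, had 21 (9 and 12) beside 35 and 3 sense counts. Mir8105 had 12 (4 and 8) beside 1 and 0 sense counts.

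MicroRNAs of choroid plexus and ciliated cells and microRNAs in introns of Htr2c were lower in replicate 2, with a median log2 ratio of -2.08 over 11 genes. The Htr2c genes, Mir764 (-0.82), Mir1912 (-2.60), Mir1264, Mir1298, Mir448 and Gm22650 (0.06), were grouped after their values were seen, and Gm24627 of the same gene had 0 counts. The intervals of 9 of the 11 lay below 0, which argues against counting error for these 9 if reads are independent. Amplified reads are not independent molecules, so the intervals do not exclude it. Counting error is left open for Mir211 (15 and 6 counts) and Gm22650 (23 and 13), so it is undecided for the group as a whole. A linear GC trend over all genes is argued against as the whole cause. Its slope was 0.06 ± 0.05 (SE) per 10% of GC. This is too flat for the group's median GC of 47.6% against 52.3% to matter, and removal of the trend left the median at -2.06. A different share of choroid plexus or ciliated epithelium in the 2 pools may account for the difference but was not tested independently, since the 0.03 percentile of the list fixed beforehand is the observation itself, with Mir204, its most abundant gene, 4.24-fold lower. Among the 9 genes with intervals below 0, log2 ratios ran from -0.82 (Mir764) to -5.32 (Mir1298), so 1 equal shift does not describe the group. This range does not decide on tissue share, since the level of each gene in the other cells of the pools is not known. The explanation stays open, since neurons also express Htr2c, the labels record no dissection detail, and no biological explanation could be tested within 1 group.

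The log2 ratio varied within the Mir379 to Mir410 array, whose members are thought to be made from 1 long transcript, with an SD of 0.71. The SD of 0.99 for other genes was not matched on counts and gives no comparison. The SD over 34 members was 6.50 times that expected from counting, which argues against counting error. A shift of the whole array by 1 amount adds the same to every member and cannot by itself give the spread: Mir543 (2.65 to 2.77) and Mir539 (-1.24 to -0.87) lay apart, and the intervals of 2 members included the median of 0.02. A linear effect of precursor GC content is argued against, since the trend over all genes removed 2.00% of the variance and a line fitted within the array took 2.88%. Differences in processing, in adapter ligation or in stability of single microRNAs may remain as explanations and were not tested, and the design gives no biological explanation to test.

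Some microRNAs with their mature sequence at more than 1 locus had few counts, as the copies of Mir124a, a hallmark neuronal microRNA, summed to 12 and 20 counts, and those of Mir9 to 511 and 234. The copies of Mir26a had 210 and 64 counts while Mir26b, at a single locus, had 41498 and 7701. Other families with several loci had many counts, with 47040 and 10285 for the Mir128 copies, 20346 and 30336 for Mir138 and 37156 and 16626 for the let-7 copies, and Mir124a, Mir9, Mir128 and Mir138 have no single-copy relative and stayed out of the test. Multi-mapping reads are not counted in genes, so reads that match several copies equally are lost by design. How much of the low counts this loss explains is not known. The summed copies lay below the mean of their single-copy relatives in 9 of 10 families, Mir181 being the exception (exact two-sided sign test p = 0.0215). The sign test takes either order as equally likely. Copies and relatives can differ in true abundance, so the test does not show that reads were lost. The result was 9 of 10 both with and without low-count relatives. Low abundance in this tissue cannot be told apart from the loss of multi-mapping reads, for single families or for the 10 families as a set. Multi-mapping reads made up 39.0% of all reads and are not divided by gene. The low counts therefore do not show that Mir124a or Mir9 was scarce.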

How the results depend on the processing

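The removal of a GC trend and the exclusion of genes with shared bases were chosen after seeing the data, and the other alternatives were fixed beforehand. No paired analysis was possible because the labels give 1 group. With total counts as library sizes, Mir382 and Mir652, both called, changed direction. Medians that were not called changed sign in some alternatives. Leaving out either replicate could not move a share beyond the SD of 2 values, and rescaling moves every gene alike and leaves percentiles as they are, so neither tests stability. The cause was not tested for the changes that follow, unless it is part of the alternative. Without strand, reads of genes that overlap on opposite strands are lost: the 10 leading genes held 55.7% of counts, and the lists held 0.000108% (oligodendrocyte), 0.00452% (red blood cell), 0.506% (blood vessel), 0.20% (astrocyte), 1.06% (mir-17 clusters) and 0.250% (Sfmbt2 repeats), and 26 detected genes were no longer detected. Without Mirlet7b in the denominator the shares were 48.8% (10 leading genes), 19.6% (let-7), 24.1% (Dlk1-Dio3), 0.209% (astrocyte), 1.11% (mir-17 clusters), 0.261% (Sfmbt2 repeats) and 3.78% (1 mature sequence at several loci). With 1 count in both libraries, 649 genes were detected. Pearson's r was 0.981 with no filter and 0.946 at a summed count of at least 200. DESeq2's median gene-wise coefficient of variation was 0.209, against 0.415 for edgeR's common value. The astrocyte median lost its call at a summed count of at least 200 (0.45) and without genes with shared bases (0.14). The median of genes with 1 mature sequence at several loci left the central 95% of random lists at a summed count of at least 200 (0.25) and with the GC trend removed (0.30). Depth limits genes near the floor of 0.630 and 1.05 CPM.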

Other observations

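Of the tests in this part, the comparison of copies was chosen after its values had been seen, while the test of neighbouring genes was set before its result.

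Neighbouring microRNA genes on 1 strand may move together between the 2 pools. Over 81 pairs within 10 kb, from 128 genes outside the Mir379 to Mir410 array, the mean absolute difference in log2 ratio was 0.75, against 1.07 when the ratios were shuffled among the same genes (central 95% of shuffles 0.93 to 1.20). Of 10000 shuffles, 0 were as small. The array was left out, so this result does not cover it. Its own members ran from -1.21 to 2.71 with an SD of 0.71. Neighbours can be similar in sequence, so shared transcription and shared sequence stay open.

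Copies of 1 mature sequence at different loci may also move together. Over 21 pairs from 42 genes, all 21 on different chromosomes, the mean absolute difference was 0.57, against 1.05 when shuffled (0.80 to 1.28), and 0 of 10000 shuffles were as small. Mir138-1 and Mir138-2 gave 1.5 and 1.33, Mir129-1 and Mir129-2 gave 1.94 and 1.22, and Mir128-1 and Mir128-2 gave -1.42 and -1.09. Others differed, with Mir218-1 and Mir218-2 at -2.02 and 0.29, Mir24-1 and Mir24-2 at 1.03 and -1.18, and Mir26a-1 and Mir26a-2 at -1.60 and -0.32, and 5 of the 21 pairs had opposite signs. All 44 tested genes with 1 mature sequence at several loci share at least 20 bases with another gene and are uncertain. The counts of 2 copies may therefore not be independent, and the shuffles do not allow for this. A difference that follows the sequence and a shared cell type both stay open.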
